A study of Mus musculus with 6 samples.

How the data were processed

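RNA from the orbitofrontal cortex of C57BL/6 mice aged 12 weeks was profiled in 6 libraries made with a strand-preserving kit, per the labels' protocols. The control group held 3 libraries from mice given a scrambled short hairpin RNA (shRNA). The knockdown group held 3 libraries from mice given a lentiviral shRNA against the back-splice junction of circHomer1a, a circular RNA made from the Homer1 gene. The labels do not state that the 3 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

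Both deposited tables held FPKM values (fragments scaled by feature length and by the number of mapped fragments), per the file headers. FastQC, cutadapt, HISAT2 and StringTie were named without versions in the submitters' processing notes. The genome build and annotation release were not given in the sources used here. Of the 13348 listed genes, 13333 had an identifier in GENCODE M21 (mouse assembly GRCm38), and 12242 of these had exactly the same coordinates. Coordinates below are those of the deposited tables.

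The deposited tables listed 13348 genes and 24676 transcripts, all of the protein-coding type. One line of each table was empty and was not analysed here. Every listed feature had a mean FPKM above 0.5 in at least 1 group, so a feature low in both groups was not listed, and circular RNA was not among the listed features. In 446 genes with 2 or more transcripts, all of them listed and with a gene value above 0 in control 1, the gene FPKM equalled the length-weighted transcript sum divided by the union exon length, within 1%. The plain sum of transcript FPKM met the same tolerance in 40 of these genes. In genes of this form, a gene value depends on the fragments assigned to the gene as a whole. Moves of fragments between transcripts of one gene leave it unchanged, while transcript values and their plain sum can change.

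Read depth was unknown, because the low values showed no whole-read steps, so no count test was used and no counting interval was given. Precision was taken from the replicates. The median half-width of the 95% interval of a gene's log2 fold change was 0.29.

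Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, for features with a mean of at least 1 FPKM over the 6 libraries, with an intensity trend in the variance and Benjamini-Hochberg adjustment at 0.05. This left 11961 genes and 18476 transcripts. Fold changes are knockdown minus control on that scale, which understates the change of low features. Transcript usage was tested with diffSplice (Simes p per gene) in 4091 genes with 2 or more tested transcripts. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated per list and with fry. Of 26 lists, 25 had at least 5 measured members. The list of lymphocyte and antigen presentation genes had fewer and was not tested. A list score is the median, over members, of log2(FPKM + 1) minus the member's mean over the 6 libraries. Single values were compared by two-sided exact permutation tests, whose smallest possible p is 0.1.

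The lists, the main tests, the naming rule and most alternatives were fixed before the data were examined. The rule named Homer1 and its transcripts, 10 genes per direction (by the smallest unadjusted p where fewer than 5 passed), up to 4 members per list by p, and the 5 transcripts and 5 usage genes with the smallest p. A few items that the rule named are not reported here; they stay in the counts. Alternatives covered the pseudocount, the filter, the scaling, the variance model, library weights, a replicate block and each library left out. Scaling alternatives were a common sum for every library, median-of-ratios factors and quantile normalization. A gene value made as the sum of its listed transcripts was added after seeing the data.

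The same functions were tested on simulated data, made by shuffling each feature's residuals over the libraries in 20 draws. For knockdown against control over 11961 genes, 21.5% of genes changed 1.5-fold were called, 69.2% of those changed 2-fold and 95% of those changed 4-fold. Over 18476 transcripts, the shares were 0.3%, 8.5% and 49.9%. These folds are of FPKM + 1, so in low features the same fold of FPKM would be called less often. With no change, 0 genes and 0 transcripts were called in each draw. Residuals were taken within the real groups and shuffled one feature at a time. A transcript on in 3 libraries and near zero in the other 3 loses that form, so the draws give no baseline for such transcripts. Other splits of the real libraries into groups of 3 called 0 to 5 genes and 5 to 21 transcripts. The usage test did not keep its error rate: with no change it called 1 to 10 genes (median 2.5), and at least 1 in 20 of 20 draws. Of 1000 genes with transcripts moved apart, 487 were recovered. At most 1 list was called in a draw with no change, but shuffling removes the correlation between features. The draws therefore say nothing of lists whose members vary together, or of transcripts of one gene that do. Figures were drawn with matplotlib 3.10.9.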

Results

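Gene expression in the mouse orbitofrontal cortex was compared between 3 control libraries and 3 libraries with circHomer1a knockdown, to find which transcripts differ when this circular RNA is targeted. The FPKM values of listed genes summed to between 256047 (knockdown 1) and 285833 (control 2). Mean Spearman correlation with the other libraries, taken across genes, was lowest for control 2 (0.957) and highest for control 1 (0.971).

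The Homer1 gene, which encodes a postsynaptic scaffold protein, was at similar mean levels in both groups. The gene (ENSMUSG00000007617.18, chromosome 13, 93299635 to 93405129, plus strand) was at 11.0 ± 1.79 FPKM in control and 11.0 ± 4.56 FPKM in knockdown libraries (SD, n = 3 each). Its log2 fold change was -0.06 (95% interval -0.66 to 0.55, limma adjusted p = 0.986, two-sided exact permutation p = 1). Homer1-204, a transcript of 5 exons and 186 codons that ends at 93360462, was at 8.27 ± 1.81 and 9.39 ± 2.81 FPKM. Homer1-203, of 10 exons and 366 codons, ranged from 3.23 FPKM in knockdown 1 to 24.4 FPKM in knockdown 2. Homer1-202 lay between 7.36 and 9.31 FPKM in 5 libraries and at 0.000332 FPKM in knockdown 3. Homer1-207 was the only one whose groups did not overlap, at 1.10 ± 0.576 and 1.94 ± 0.654 FPKM (limma adjusted p = 0.950, two-sided exact permutation p = 0.1). Homer1-205 was at 2.80 ± 1.43 and 1.43 ± 1.00 FPKM. The remaining listed transcript, too low to be tested, was at 0, 0 and 1.70 FPKM in control 1, 2 and 3 and at 0.678, 0 and 1.51 FPKM in knockdown 1, 2 and 3. These values are those of linear gene and transcript models. None measures the circular RNA by itself, so they do not check the knockdown. The sign of the gene's fold change turned with array weights (0.13) and when control 1, control 3, knockdown 1 or knockdown 3 was left out (up to 0.17).

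**Figure D1:**
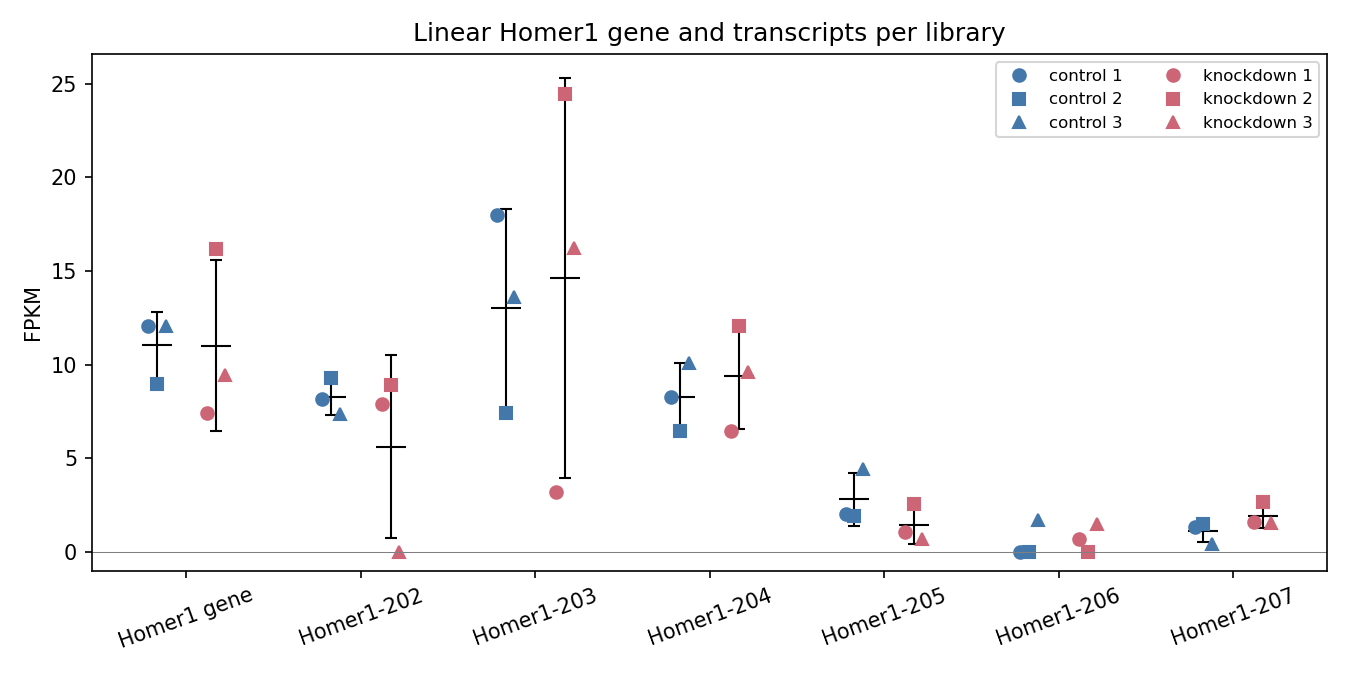
FPKM (y axis) of the Homer1 gene and its 6 listed transcripts in each of the 6 libraries; points are libraries, black dashes and bars are group means and SD (n = 3), left out where a library is listed at 0. The groups overlap for the gene, and Homer1-202 is at 0.000332 FPKM in knockdown 3.

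No gene total passed the threshold: limma called 0 of 11961 genes, with a smallest adjusted p of 0.0692, and 427 genes had an unadjusted p under 0.05 where chance gives 598. The groups did not overlap in 7.92% of genes, where chance gives 10%. The genes below are those with the smallest p and did not pass. Chmp3, an ESCRT-III component of membrane scission, was at 9.24 ± 1.72 FPKM in control and 26.9 ± 0.718 FPKM in knockdown libraries (log2 fold change 1.46, adjusted p = 0.0692). Cyld, a deubiquitinase, was at 3.18 ± 0.773 and 9.38 ± 0.918 FPKM, and Ttll7, a tubulin polyglutamylase, at 4.67 ± 1.83 and 16.4 ± 0.601 FPKM. Ociad2 was at 10.4 ± 1.04 and 24.7 ± 3.89 FPKM. The circadian transcription factor Clock was at 1.87 ± 0.196 and 3.59 ± 0.433 FPKM, with Cuedc1, Ctgf, Lgals3bp and Mlxip also higher in each knockdown library than in any control.

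In the other direction, Rprd1b, a regulator of RNA polymerase II, was at 2.83 ± 0.242 FPKM in control and 0.620 ± 0.152 FPKM in knockdown libraries (log2 fold change -1.24, adjusted p = 0.0692). The Polycomb gene Phc3 was at 2.58 ± 0.564 and 0.408 ± 0.0433 FPKM (log2 fold change -1.34, adjusted p = 0.0777). Creb1, an activity-dependent transcription factor, was at 2.04 ± 0.215 and 0.477 ± 0.282 FPKM, and Cpne6 at 24.7 ± 0.266 and 16.9 ± 0.988 FPKM. B3galnt2, Mlx, Gpx3, Ednrb, Smpd4 and Usf3 completed the 10, with log2 fold changes from -1.07 (Usf3) to -0.59 (Mlx). Some of these genes passed under another choice. Chmp3 did after rescaling every library to one common sum (limma adjusted p = 0.048), with array weights (0.0216) and without control 2 (0.0208), Rprd1b and Phc3 with array weights (0.0396 for both), and Ttll7 without control 1 (0.017). As a sum of listed transcripts, a choice made after seeing the data, Chmp3 (0.0295) and Phc3 (0.0276) passed.

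Single transcripts passed the threshold where gene totals did not. Of 18476 transcripts, limma called 19 in 18 genes, 11 higher and 8 lower in knockdown libraries, and 704 had an unadjusted p under 0.05 where chance gives 924. Other splits of the 6 libraries into groups of 3 called between 5 and 21 transcripts, so the count of 19 does not set the real split apart. With a replicate block 0 transcripts were called. Hsp90aa1-201, from a cytosolic chaperone gene, fell from 278 ± 47.2 to 6.38 ± 2.18 FPKM (log2 fold change -5.27, adjusted p = 0.0128), with gene totals of 263 ± 16.6 and 240 ± 53.8 FPKM. Mgll-204, from the gene of the 2-arachidonoylglycerol hydrolase, fell from 38.8 ± 7.62 to 3.19 ± 0.717 FPKM (adjusted p = 0.0191), with totals of 44.7 ± 3.49 and 44.8 ± 4.44 FPKM. Abi1-204 was listed at 0 in each control and at 7.39, 8.79 and 7.01 FPKM in knockdown 1, 2 and 3 (adjusted p = 0.0128). Actr8-204 was at 0.0184, 0.0199 and 0 FPKM in control 1, 2 and 3 and at 11.0 ± 3.10 FPKM in knockdown libraries (adjusted p = 0.0197). Over the 19 transcripts the median absolute log2 fold change was 2.41, against 0.08 for their gene totals. The call count was 32 without control 2, 29 without control 3 and 11 without knockdown 2, and between 3 and 10 of the 19 remained when a library was left out. Without knockdown 2, Abi1-204 and Mgll-204 (adjusted p = 0.0521 for both) and Actr8-204 (0.0821) lost their call. Their log2 fold changes were then 3.04, -3.24 and 3.51, against 3.12, -3.25 and 3.54 with all 6 libraries. Actr8-204 also lost its call with a mean of at least 5 FPKM (adjusted p = 0.374), at an unchanged 3.54.

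**Figure D2:**
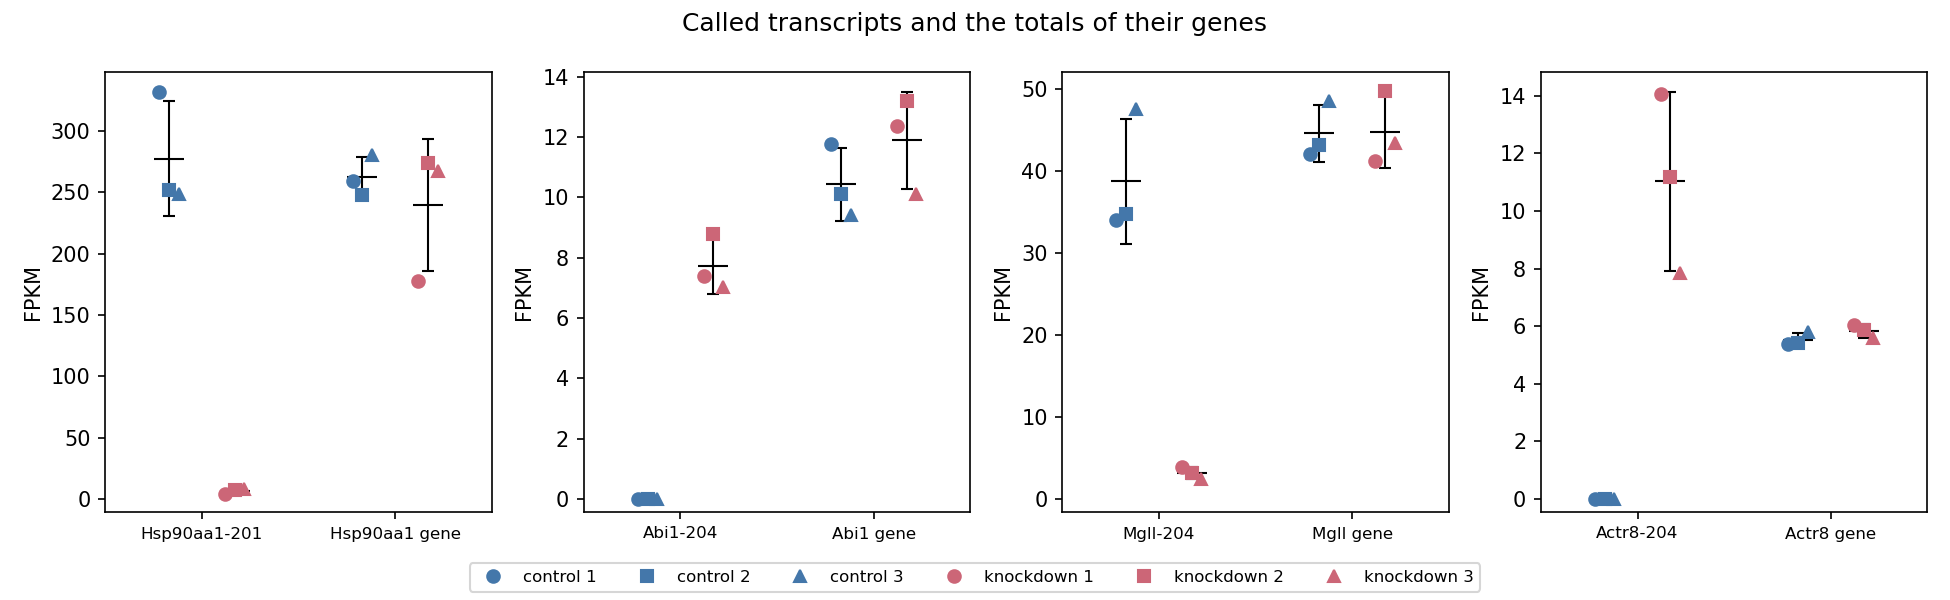
FPKM (y axes, 1 scale per panel) of 4 of the transcripts with the smallest p and of their genes in the 6 libraries; points are libraries, black dashes and bars are group means and SD (n = 3), left out where a library is listed at 0. Each transcript separates the groups, such as Mgll-204 at 38.8 and 3.19 FPKM, while the Mgll totals are 44.7 and 44.8 FPKM.

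Transcript usage, the relative level of transcripts within a gene, passed the threshold in 47 of 4091 genes (diffSplice). With no change simulated, this test still called 1 to 10 genes per draw, so the adjusted p-values below are too small. That simulation shuffled each transcript alone and lost any joint movement of transcripts of one gene, so it gives no baseline for the 47. Other splits of the 6 libraries into groups of 3 called between 28 and 65 genes. In Clock (adjusted p = 1.22e-06), Clock-204 was at 4.02 ± 0.403 and 0.506 ± 0.112 FPKM, and Clock-205 at 0.196 ± 0.0994 and 4.33 ± 0.506 FPKM. In Crmp1, a semaphorin signalling gene of axons, Crmp1-202 fell from 28.0 ± 3.25 to 2.06 ± 0.816 FPKM and Crmp1-201 rose from 20.6 ± 1.53 to 48.2 ± 1.20 FPKM. In the RNA methyltransferase gene Nsun6, Nsun6-201 was listed at 0 in each control and Nsun6-208 at 0 in knockdown 1 and 2. In the proteasome gene Psma4, Psma4-207 was listed at 0 in each control and at 3.52, 3.65 and 3.46 FPKM in the knockdown libraries. Psma4-201, its other tested transcript, held most of the level in both groups, at 83.2 ± 7.10 and 76.1 ± 3.52 FPKM, and there the groups overlapped. Leaving out any 1 library gave between 74 (knockdown 2) and 110 (control 3) genes, and between 32 and 38 of the 47 remained.

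Among 25 gene lists, 7 passed with the preset correlation, 2 higher and 5 lower in knockdown libraries (3 and 4 after quantile normalization). None passed with an estimated correlation, where each of the 7 had adjusted p = 0.787, and none with fry. The estimated correlation of the 7 lay between 0.27 (immediate early genes) and 0.92 (ribosomal proteins), far above the preset 0.01. Members of a list thus varied together, and the adjusted p-values below, taken with the preset, are too small. Two-sided exact permutation p of the 7 list scores lay between 0.2 (ribosomal proteins and myelin markers) and 0.5 (interferon response). No member of any list passed over all genes tested, and 1 passed adjusted over the list alone.

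Myelin and oligodendrocyte markers were higher, with a positive fold change in 20 of 20 members and a median of 0.31 (adjusted p = 7.56e-11). Mag, a myelin adhesion protein, was at 56.2 ± 8.56 and 73.9 ± 11.3 FPKM, and Ermn at 31.3 ± 6.44 and 42.9 ± 5.87 FPKM. Myelin scores of the groups overlapped, at 0.05, -0.40 and -0.16 in control 1, 2 and 3 and 0.41, -0.03 and 0.17 in knockdown 1, 2 and 3. With array weights the median was 0.19 (adjusted p = 0.000114). Interferon response genes were higher in 16 of 18 members (median 0.30, adjusted p = 0.00327), but the list's score was 0.76 in knockdown 1 and between -0.19 and -0.02 in the other 5 libraries. Without knockdown 1 the list had a median of -0.02 (adjusted p = 0.783), and without control 1 its adjusted p was 0.137. With array weights it was 0.0527, and with genes summed from listed transcripts, chosen after seeing the data, 0.13. Lgals3bp passed adjusted over the list alone (limma adjusted p = 0.0267), at 2.28 ± 0.385 and 4.93 ± 1.24 FPKM, but its fold change was -0.24 when genes were summed from listed transcripts.

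Cytosolic ribosomal proteins were lower, with a negative fold change in 76 of 76 members and a median of -0.19 (adjusted p = 3.07e-17). Rps2 was at 170 ± 18.1 and 141 ± 10.6 FPKM. Nuclear-encoded oxidative phosphorylation genes were lower in 56 of 64 members (median -0.12, adjusted p = 4.73e-07) and mitochondrially encoded genes in 12 of 13 (median -0.19, adjusted p = 0.00327). Control 2 had the highest score of these lists, 0.36, 0.20 and 0.29. Without it, the ribosomal median was -0.06 (adjusted p = 0.00467), and the other lists lost their call, with medians of -0.06 (0.0514) and -0.10 (0.0579). They also lost it without knockdown 1, with medians of -0.06 (0.0666) and -0.10 (0.312). Larger differences came without control 1 for the ribosomal (-0.29) and oxidative phosphorylation lists (-0.23), and without knockdown 3 for the mitochondrial list (-0.30). After quantile normalization the ribosomal median was -0.12 (adjusted p = 6.61e-10) and the oxidative phosphorylation median -0.06 (0.0116). Rescaling every library to one common sum gave -0.13 and -0.06, with the median of all genes moved from 0.02 to 0.08. After quantile normalization the mitochondrial list had a median of 0 (adjusted p = 0.421), but 12 of its 13 genes were among the 13 highest values of every library, which this step makes nearly equal, so the loss says little about the list. Erythrocyte genes were lower in 6 of 6 members (median -0.78, adjusted p = 0.009), with scores of -0.43, 1.58 and -0.04 in control 1, 2 and 3 and -0.71, -0.61 and 0.15 in knockdown 1, 2 and 3. Their median was -0.15 without control 2 (adjusted p = 0.411), -0.61 without knockdown 1 (0.107) and -1.20 without control 1 (0.00124).

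Activity-regulated immediate early genes were lower by the test (adjusted p = 0.0279), with 17 of 29 members negative and a median of -0.03. Per1 was at 18.7 ± 0.457 and 14.2 ± 2.42 FPKM and Nr4a1 at 43.2 ± 7.54 and 34.5 ± 1.33 FPKM. The median was -0.08 without control 1, -0.12 without control 2 and -0.10 without knockdown 1, where the call remained. The call was lost without control 3 (median 0.07, adjusted p = 0.579), knockdown 2 (median -0.07, 0.0634) or knockdown 3 (median -0.07, 0.07). It was also lost with a mean of at least 5 FPKM (median -0.0009, 0.252) and with array weights (median -0.06, 0.0527). Camera on ranks (adjusted p = 0.0511) and genes summed from listed transcripts (0.111), the last chosen after seeing the data, lost it too.

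**Figure D3:**
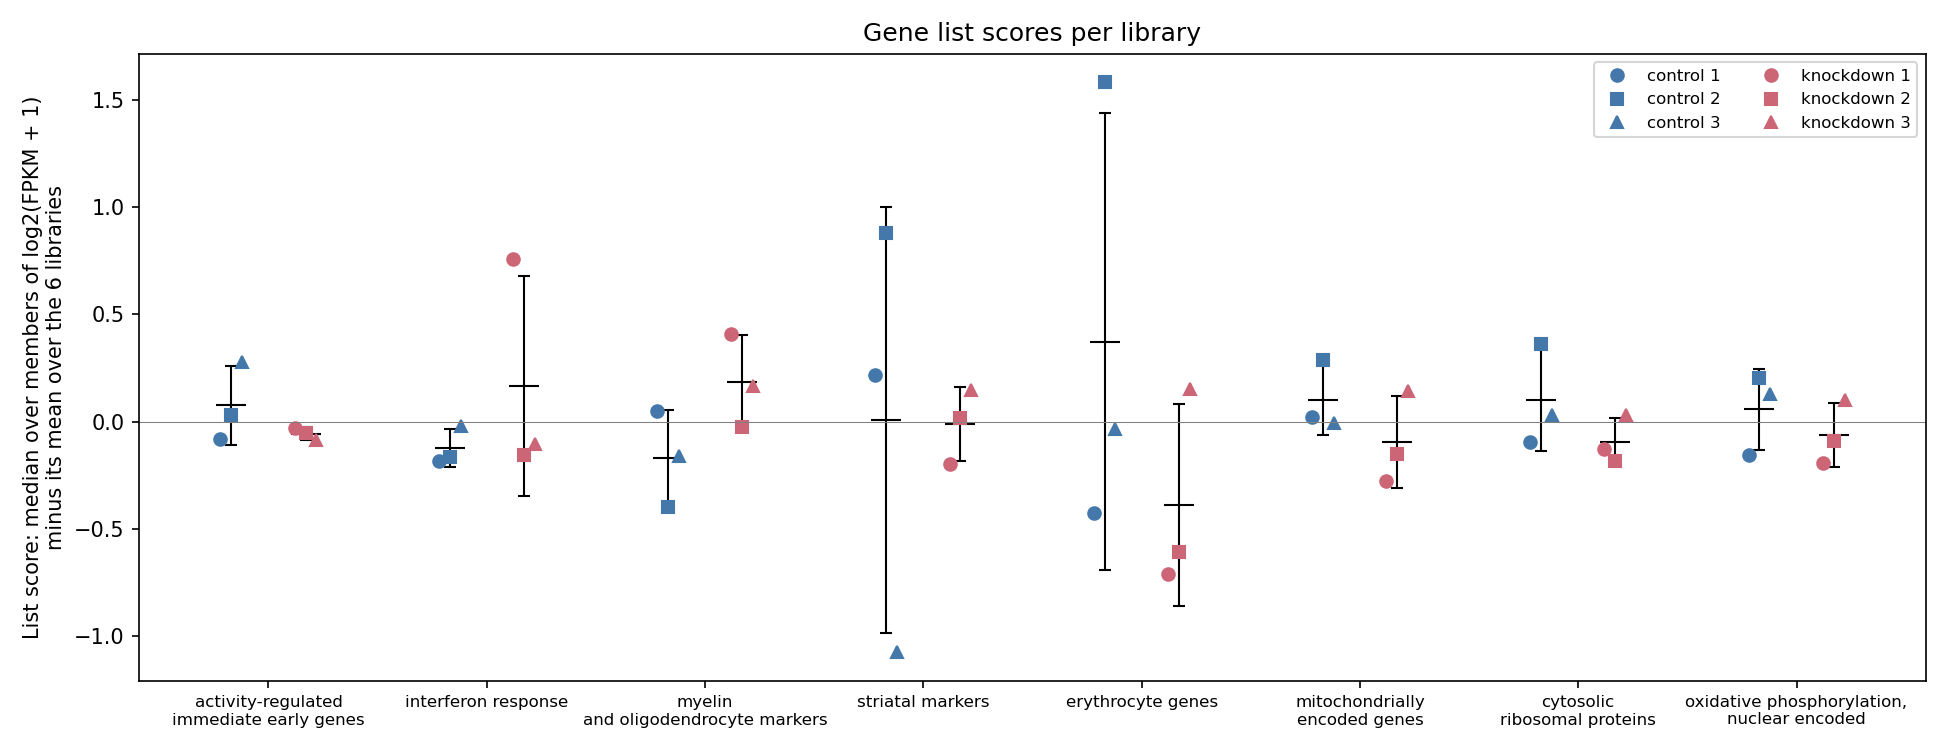
Score (y axis, log2 units) of the 7 lists past the threshold with a preset correlation and of striatal markers in each library; points are libraries, black dashes and bars are group means and SD (n = 3). Single libraries stand apart, such as knockdown 1 for the interferon response (0.76) and control 2 for erythrocyte genes (1.58).

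No synaptic list passed with all 6 libraries and the settings of the other lists above. Presynaptic vesicle release passed as higher after quantile normalization (adjusted p = 0.0104) and without control 3 (0.00595), and postsynaptic density scaffolds as lower without knockdown 2 (0.0267). Medians of log2 fold changes follow, each with its range in brackets when any 1 library was left out. The median was -0.01 (-0.07 to 0.05) for postsynaptic density scaffolds, 0.02 (-0.02 to 0.07) for ionotropic glutamate receptors, 0.07 (0.03 to 0.12) for Homer-bound glutamate receptor and calcium-store genes, 0.08 (0.03 to 0.15) for GABA signalling and 0.09 (0.04 to 0.14) for presynaptic vesicle release. Dlg1, a synaptic scaffold, was at 14.7 ± 1.90 and 9.94 ± 2.14 FPKM, and Gabra5, a GABA receptor subunit, at 11.1 ± 0.341 and 14.7 ± 1.55 FPKM. Medians were 0.07 (-0.01 to 0.16) for neuronal RNA-binding proteins, 0.01 (-0.11 to 0.05) for excitatory neuron markers and -0.06 (-0.20 to 0.06) for interneuron markers. The median was 0.02 (0.01 to 0.07) for astrocyte markers, 0.16 (0.09 to 0.34) for reactive astrocyte genes, -0.06 (-0.14 to 0.01) for microglia markers and 0.01 (-0.04 to 0.07) for oligodendrocyte precursor markers. It was 0.08 (0.00022 to 0.18) for endothelial, -0.10 (-0.29 to 0.03) for meningeal, -0.05 (-0.61 to 0.24) for choroid plexus and -0.24 (-0.36 to -0.03) for olfactory markers, and -0.03 (-0.14 to 0.002) for heat shock genes. Some of these other lists passed under another choice. Without control 3, reactive astrocyte (adjusted p = 0.00627) and endothelial markers (0.0153) were higher, and interneuron (0.0273), choroid plexus (0.0408) and olfactory markers (0.00595) lower. Without knockdown 1, endothelial markers were higher (0.0241) and choroid plexus markers lower (0.000609). Excitatory neuron markers were lower without control 2 (0.0199) and heat shock genes without knockdown 2 (0.000176). After rescaling every library to one common sum, interneuron (0.0273), meningeal (0.0124) and olfactory markers (0.00268) were lower, and olfactory markers also with no filter (0.0195). With all 6 libraries and the settings above, adjusted p over these lists and the striatal markers lay between 0.123 (olfactory markers) and 0.831 (ionotropic glutamate receptors). Striatal markers had a median of -0.02, with scores of 0.88 in control 2 and -1.08 in control 3, so that leaving out control 2 gave 0.39 (adjusted p = 0.00149) and leaving out control 3 gave -0.54 (adjusted p = 5.29e-11).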

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

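The sum of listed transcripts as gene value was chosen after seeing the data. Filters and scaling: with no filter 92 genes shifted usage. With a mean of at least 5 FPKM, 8 transcripts and 13 usage genes were called among fewer features. Rescaling every library to one common sum put more features above the minimum and gave 1 gene, 29 transcripts and 86 usage genes. Variance model and weights: 44 transcripts were called with no intensity trend, and array weights gave 3 genes and a Homer1 log2 fold change of 0.13. Lists passing numbered 0 with an estimated correlation and 0 with fry. Gene values summed from listed transcripts gave 4 genes and turned the sign of Lgals3bp (-0.24), Slc17a7 (0.088), Matn4 (-0.0035) and Ppp1r1b (0.19). The cause of these differences was not tested, and the number of features was only recorded with each choice.

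The replicate block called 0 transcripts, 0 genes, 37 usage genes and 7 lists. Genes with an unadjusted limma p under 0.05 numbered 552 with the block and 427 without it. Deviations of same-numbered libraries correlated at 0.184, -0.127 and -0.0708, and control 2 correlated best with knockdown 3 (0.269). Deviations cancel within a group of 3, so these values constrain each other and cannot exclude a shared batch. Only a number links the samples in their titles, and whether they were paired stays open.

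With each library left out in turn, calls ranged from 0 to 3 genes, 11 to 32 transcripts, 74 to 110 usage genes and 5 to 13 lists. Log2 fold changes ranged from -0.34 to 0.17 for Homer1, -0.000479 to 0.24 for Cacna1d, -0.99 to 0.26 for Ccdc153, -0.80 to 0.11 for Pdyn, -0.96 to 0.082 for Serpina9 and -0.44 to 0.022 for Trh. They ranged from -0.30 to 0.027 for Tshz1, -0.037 to 0.37 for Bmp6, -0.44 to 0.11 for Igfbp2, -0.19 to 0.52 for Foxj1 and -0.46 to 0.022 for Doc2g. Adjusted p ranged from 5.29e-11 to 0.882 for striatal markers and from 0.00117 to 0.579 for immediate early genes, each with a turned direction. The alternative count tests were not run, as the tables hold no counts. Read depth was unknown.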

Other observations

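The counts of calls over other splits, the comparison of called transcripts with gene totals, and the test of annotated transcript numbers were chosen only after the results were seen. Among markers of other cell types, values outside any list call stood apart in single genes, none of which passed over all genes. The microglial receptor Cx3cr1 was at 2.59 ± 0.493 FPKM in control and 7.00 ± 2.66 FPKM in knockdown libraries (limma adjusted p = 0.0904, adjusted over the list alone). Its list went the other way, with a negative fold change in 16 of 21 measured microglia markers (median -0.06). Calb2, an interneuron calcium-binding protein, was at 8.01 ± 0.426 and 4.60 ± 1.27 FPKM (limma adjusted p = 0.0822 over the list alone), and the cortical transcription factor Foxp1 at 7.06 ± 3.37 and 2.63 ± 0.484 FPKM (limma adjusted p = 0.206 over the list alone). P2ry12-202, a transcript of a microglial receptor chosen here after its values were seen, was at 12.1, 15.0 and 7.28 FPKM in control 1, 2 and 3 and at 0.000624, 0.042 and 0 FPKM in knockdown 1, 2 and 3, while the P2ry12 total was 11.5 ± 1.17 and 11.9 ± 0.677 FPKM.

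The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split called 0 genes, a count that each of the 10 splits reaches whatever the data, so this comparison tests nothing (5 in the highest other). At least as many transcripts were called in 3 splits (real 19, highest other 21), as many usage genes in 4 (real 47, highest other 65) and as many lists in 10 (real 7, highest other 17). The 1 to 10 usage genes called in simulated data with no change give no baseline for the 47. The split that set control 1, knockdown 1 and knockdown 2 against the rest had 1994 genes at an unadjusted limma p under 0.05, against 427 for the real split. It was the highest of the 10 and was picked after the values were seen. Whether it reflects a structure of the samples other than the group was not tested.

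The first pattern is the near all-or-none behaviour of single transcripts. A count of transcripts under 0.5 FPKM in 3 libraries and at 2 FPKM or more in the other 3 gave 29 along the real split and at most 27 along any other, so it remained open whether such switches follow the group. The gene totals of the 19 called transcripts changed by a median of 0.08 log2 units against 2.41 for the transcripts, a ratio of 0.0348. For most of them, fragments moved between transcripts of one gene would give such a ratio. The 19 were picked for their own change and not that of the gene, so a small ratio is partly built in. It also arises where a transcript is a small part of its gene. Psma4-207, for one, was at 0 FPKM in controls and 3.54 FPKM in knockdown libraries, with gene totals of 41.7 and 39.3 FPKM. The ratio therefore does not show that fragments were moved. Such moves do not account for Chmp3-201 and Phc3-209, whose gene totals moved too (1.46 and -1.34). The totals of Clock-205 (0.68) and Rassf2-202 (0.59), the last named after its values were seen, were also not kept. A regulated change of transcript choice in the knockdown would give the same ratio and was not tested apart from such moves.

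The second pattern is the lower ribosomal protein list and the higher myelin list. Without control 2 the ribosomal median went from -0.188 to -0.0600, so control 2 may carry most of it, although the call with a preset correlation remained. The ribosomal difference was as large in 1 other split (0.28 against -0.19), that of control 1, knockdown 1 and knockdown 2, and the myelin difference in 1 other split (-0.39 against 0.31), that of control 1, knockdown 1 and knockdown 3. This met what was set beforehand for a library-wide axis unrelated to the group. A match in any 1 other split was enough, which is likely without such an axis too, so meeting it says little for one. Since the lists matched in different splits, which was weighed only after the values were seen, such an axis stays open. The myelin median without control 2 was 0.23 against 0.31, which leaves open how much that library adds. A difference in white matter taken at dissection, or an effect of the knockdown, was not tested.

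The third pattern is that gene totals such as Chmp3 and Phc3 lay far apart with little spread. The 20 named genes were picked by the smallest p, which itself favours large differences with little spread. Of 11961 genes, 427 had an unadjusted limma p under 0.05 where chance gives 598. Selection from many genes may thus be enough to give this pattern. Fragments shared with an overlapping gene are argued against, since 0 of the 20 named genes overlapped exons of another gene on the same strand in GENCODE M21. The share in other genes was 8.76%, and the difference in shares itself had a two-sided Fisher exact p of 0.251. None of the 20 had a single annotated transcript, against 9.54% of other genes (two-sided Fisher exact p = 0.251). No lower count was possible, so with 20 genes this test could not have shown a shortage of such genes. It therefore says nothing for or against an effect of transcript assignment on these totals. A gene value of the length-weighted form, met in all 446 genes checked, is left unchanged by moves of fragments between its transcripts. That form was not checked for the 20 named genes as a set. An effect of the knockdown stays open and untested, and none of these totals passed the threshold.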
